A study of Mus musculus with 12 samples.

How the data were processed

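Eyes of newborn mice (postnatal day 0.5) without RNG140 and of wild-type (WT) controls were profiled with 2 assays. RNG140 is an RNA-binding protein, the product of Caprin2. Ribosome profiling sequences the short RNA fragments that ribosomes protect from nuclease, so its counts reflect how many ribosomes sat on an mRNA. RNA-seq of the same tissue measures the mRNA itself. Each of the 4 groups (footprints or mRNA, WT or knockout, KO) held 3 libraries, 12 in all. The labels give a number from 1 to 3 to each library and no litter, sex or batch, and they do not say whether libraries came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

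Per the labels, footprint libraries were made by RNase I digestion, ribosome pelleting, linker ligation, ribosomal RNA depletion, circularization and PCR, and mRNA libraries with an Illumina TruSeq kit. Per the submitters' processing notes, CASAVA 1.8, Bowtie2 2.3.4.2, TopHat2 2.0.9 and the mm10 mouse genome were used. The counting rule, the annotation version, the read-length filter and the treatment of reads that fit several transcripts are not given in the sources used here. The authors deposited whole-number read counts per transcript, not normalized, for 63759 UCSC transcript identifiers in each library. A second number per transcript was the same in all 12 libraries, from 16 to 33458, and was missing for 17340 transcripts that had no counts. It has no stated unit. Its remainders on division by 3 were even (33.3%, 33.1% and 33.7%), so it does not hold coding lengths in nucleotides. Coding lengths in codons would give such remainders, but other lengths would too, and which it is was not settled. It is called the listed length, printed in its own unknown unit, and short and long mean its size relative to other features.

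Counts summed to between 327847 and 5966639 in the footprint libraries and between 666464 and 1244104 in the mRNA libraries. Of the 42689 transcripts with any count, 13965 shared all 12 counts with another transcript, as isoforms counted over the same reads would. Each distinct set of 12 counts was kept once, as 1 feature, which left 32803. Many remaining features are overlapping transcripts that share reads, so counts of changed features exceed the number of changed genes and features are not independent. The planned reduction to 1 feature per gene was not made, because neither the files nor the reference tables used here pair the identifiers with genes. For the same reason features are described by listed length and abundance. The expression of the targeted gene itself, Caprin2, of Caprin1, of crystallins and of 29 gene lists fixed in advance was not analysed here. The knockout therefore rests on the labels alone.

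The main tests, the rule for naming and most alternatives were fixed before the data were examined. mRNA and footprints were each tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM scaling, edgeR's default low-count filter and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was called a change. Translation efficiency, the ratio of footprints to mRNA, was tested as the assay-by-genotype interaction in 1 edgeR model of all 12 libraries, for features with at least 10 counts summed over the libraries of each assay. Fold changes are log2 of KO over WT, with standard errors (SE) derived from the F statistic. Levels are CPM, counts scaled to the library total, and log2 CPM used a prior count of 2. The listed length replaced the transcript length named in the plan. Its relation to expression was measured in each library as the slope of log2 CPM on log2 listed length over 16417 features, and as the slope of the log2 footprint to mRNA ratio, for which the footprint and mRNA library of a genotype with the same number were set together as 1 numbered sample. The labels do not say that such libraries came from the same tissue, and the number was used to join them for this ratio and in the alternatives only. Slopes and shares were compared between genotypes with two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.10. There were 7 such tests, and the smallest Benjamini-Hochberg adjusted value among them was 0.35. Correlations across features are descriptions, since features are not independent replicates.

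The naming rule took the features with the smallest adjusted p in each direction, among those past the threshold with every KO library on one side of every WT library. Because the files do not pair identifiers with names, 2 that rose and 2 that fell in mRNA are given. Within a direction, a feature whose values correlated over 0.95 with one already taken was skipped. Alternatives were another scaling (DESeq2 1.42.0 size factors), the DESeq2 test, no low-count filter, an adjusted p under 0.10, every transcript tested separately, the replicate number as a block, limma voom with sample weights, scaling within each assay, features with an average of at least 100 counts in both assays, and leaving out each replicate in turn. Added after the data were seen were removal of each library's length trend, merging of neighbouring transcripts whose values correlated over 0.95, leaving out the 10 most abundant features, and leaving out WT mRNA libraries 1 and 2 or WT footprint library 1. Where 1 WT mRNA library remained, it was assumed to vary like the other groups. Beyond translation efficiency, the relations to length of mRNA and footprints alone, the overlap of calls between assays, the features called with each replicate left out and the description of the most abundant footprint features were also added after the data were seen. Figures were drawn with matplotlib 3.10.9.

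The procedure was tested on simulated counts with the real means, depths and spread and 200 changed features. Features were drawn independently, with no length trend that differed between libraries of an assay. For mRNA, 49 of 61 features changed 4-fold were recovered (80.3%), 9 of 58 changed 2-fold (15.5%) and 0 of 81 changed 1.5-fold. For footprints, 25 of 67 changed 4-fold (37.3%), 1 of 65 changed 2-fold and 0 of 68 changed 1.5-fold were recovered. For translation efficiency, 5 of 76 changed 4-fold (6.58%), 0 of 58 changed 2-fold and 0 of 66 changed 1.5-fold were recovered. The slope was recovered with an error of at most 0.0168. No pair of libraries of a group agreed within sampling noise: the chi-square per degree of freedom of their counts lay between 1.99 and 31.8.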

Results

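To measure how loss of RNG140 changed translation in the newborn mouse eye, ribosome footprints and mRNA were counted in 3 WT and 3 KO libraries of each kind. The WT footprint libraries 1, 2 and 3 held 327847, 847125 and 5966639 counts, and the KO footprint libraries 5498069, 2266036 and 1875021. The mRNA libraries were closer in depth, with 1244104, 666464 and 728736 counts in WT and 709372, 794785 and 772633 in KO.

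Libraries of the same kind and genotype resembled each other to different degrees. The KO footprint libraries had Spearman correlations of log2 CPM across features between 0.906 and 0.928 with each other, whereas the WT footprint libraries ranged from 0.571 to 0.808. Among mRNA libraries the correlations lay between 0.814 and 0.909 within WT, between 0.821 and 0.853 within KO, and between 0.689 and 0.777 across genotypes, so the ranges within and across genotype did not overlap. Footprint libraries did not separate in this way, since WT and KO footprint libraries correlated at 0.490 to 0.876. WT footprint library 1 had the highest mean correlation with the 6 mRNA libraries (0.618), above 0.579 and 0.424 in the other WT libraries and 0.392, 0.437 and 0.480 in the KO libraries.

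**Figure D1:**
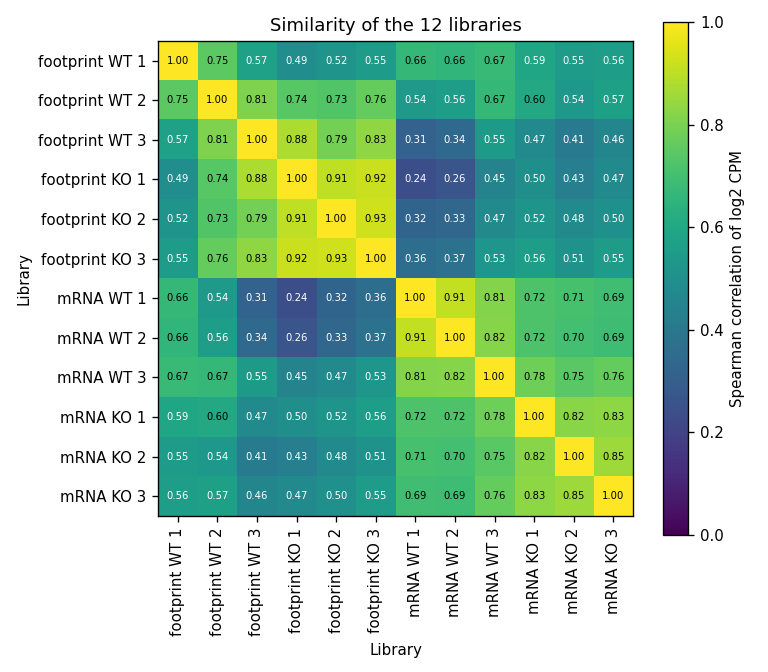
Spearman correlation of log2 CPM across features for each pair of the 12 libraries, with color and printed value on a scale from 0 to 1. The KO footprint libraries form the tightest group (0.906 to 0.928), and WT footprint library 1 lies apart from the other footprint libraries.

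The mRNA of many features differed between KO and WT eyes. Of 14131 features tested, 1294 rose and 851 fell in KO (edgeR quasi-likelihood test, adjusted p under 0.05), which together is 15.2% of those tested. The median log2 fold change was 1.41 among features that rose and -1.09 among those that fell. Features that rose were short, with a median listed length of 318, and those that fell were long, with a median of 992, against 582 for all features tested. The 3 KO libraries lay wholly above or below the 3 WT libraries in 32.2% of features, where chance gives 10% on average over splits. Features share trends of whole libraries, so a single split can lie above this without an effect of genotype. The share was not computed for other splits. When replicates were left out in turn, 460 features were called each time (360 up with a median listed length of 276, and 100 down with a median of 1072.5). The number of calls without WT library 1 was 1081, without WT library 2 1018, without WT library 3 4379, without KO library 2 925 and without KO library 3 652. It was 1281 with DESeq2. Of the 2145 calls, 2143 were tested with WT represented by library 3 alone, and 2141 of them kept their direction. Their median log2 fold change was then 1.01 for those that rose and -0.88 for those that fell. Library 3 also entered the calls, so this is not an independent check.

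The features picked by the naming rule kept their mRNA change in all 15 alternatives run on them. The alternatives reuse the libraries that picked these features, so this is not an independent check. The transcript uc007hjt.2, of listed length 78, rose from 6.69 ± 4.39 CPM in WT to 135.6 ± 9.30 in KO (SD, n = 3). Its log2 fold change was 4.54 (SE 0.39, edgeR adjusted p = 2.96e-07). It had few reads, from 2 to 81 counts per mRNA library, and its log2 fold change ran from 3.41 to 4.96 in the alternatives. The transcript uc008cro.4, of listed length 359, rose from 15.9 ± 8.05 to 183.0 ± 82.1 CPM, a log2 fold change of 3.39 (SE 0.36, edgeR adjusted p = 7.03e-06). The transcript uc007jpg.2, of listed length 1282, had 119.2 ± 28.2 CPM in WT and 25.2 ± 4.34 in KO, a log2 fold change of -2.24 (SE 0.29, edgeR adjusted p = 6.06e-05). The transcript uc008pjn.2, of listed length 992, had 235.5 ± 40.4 CPM in WT and 64.9 ± 14.0 in KO, a log2 fold change of -1.86 (SE 0.27, edgeR adjusted p = 0.000142). The files do not pair these identifiers with gene names.

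The direction of mRNA change followed length across the whole range. In the shortest quartile of features, with listed lengths from 16 to 361, 735 features rose and 63 fell, and the median log2 fold change was 0.44. In the second quartile (362 to 582) 281 rose and 114 fell, with a median of 0.08. In the third quartile (583 to 915) 166 rose and 207 fell, with a median of -0.05. In the longest quartile (916 to 33458) 112 rose and 467 fell, with a median of -0.30. Across features the Spearman correlation of log2 fold change with listed length was -0.389. It was -0.0941 when WT mRNA libraries 1 and 2 were left out, and -0.751 for features with an average of at least 100 counts in both assays.

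**Figure D2:**
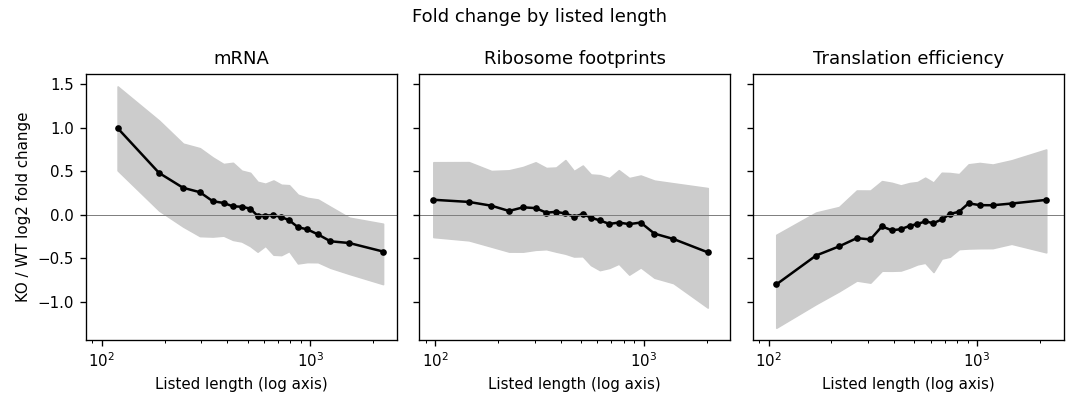
Median KO to WT log2 fold change (line and points) and its 25th to 75th percentile (grey band) in 20 bins of listed length (log axis) for mRNA, ribosome footprints and translation efficiency. The mRNA medians decline from short to long features (Spearman correlation across features -0.389), the footprint medians decline less (-0.149), and the translation efficiency medians rise (0.255).

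Of 17236 features tested in ribosome footprints, 118 rose and 75 fell in KO (edgeR, adjusted p under 0.05), or 1.12%, and 3759 had an unadjusted p under 0.05. This count is not on the same footing as that of mRNA, since in simulation the footprint test recovered 37.3% of features changed 4-fold and the mRNA test 80.3%. The KO libraries lay wholly above or below the WT libraries in 26.5% of features, where chance gives 10% on average over splits. Here too a single split can lie above this without an effect of genotype. The smallest adjusted p was 0.0217. The median log2 fold change was 2.23 among those that rose and -2.09 among those that fell, and the median listed lengths were 454.5 and 693, against 485 for all features tested. The transcript uc007jpg.2 fell from 72.2 ± 12.4 CPM to 13.6 ± 5.99 (SD, n = 3), a log2 fold change of -2.40 (SE 0.43, edgeR adjusted p = 0.0270). The transcript uc007hjt.2 rose with a log2 fold change of 2.46 (SE 0.51, edgeR adjusted p = 0.0470) and uc008cro.4 with 2.14 (SE 0.46, edgeR adjusted p = 0.0493). For uc008pjn.2 the footprint log2 fold change was -0.36 (SE 0.38, edgeR adjusted p = 0.614). The number past the threshold depended on which libraries were kept and on the model. It was 0 without WT library 2, 0 without KO library 1, 0 without KO library 2 and 9 without KO library 3. It was 500 without WT library 1 and 3057 without WT library 3. With the replicate number as a block it was 0. In the 14 alternatives run on them the log2 fold change stayed between 2.10 and 2.99 for uc007hjt.2, between 1.76 and 2.39 for uc008cro.4 and between -2.75 and -2.07 for uc007jpg.2, so their lost calls were not losses of the fold. With DESeq2, 312 features rose and 405 fell.

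Footprint fold changes also ran against length, with a Spearman correlation of -0.149 across features. The median log2 fold change was 0.11 in the shortest quartile of features (16 to 284) and -0.20 in the longest (804 to 33458). This correlation was 0.0105 without WT library 1 and 0.0438 for features with an average of at least 100 counts in both assays.

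Changes in footprints went partly with changes in mRNA. Over the 12694 features tested in both assays, log2 fold changes had a Pearson correlation of 0.468 and a Spearman correlation of 0.453, and the regression slope of footprint on mRNA change was 0.51. Of 1208 features that rose in mRNA, 35 also rose in footprints, where independent lists would share 6.76 (Fisher's exact test p = 8.31e-18). Of 752 that fell in mRNA, 35 also fell in footprints, where independent lists would share 4.09 (Fisher's exact test p = 4.22e-25). No feature was called in opposite directions. These p-values treat overlapping transcripts as independent and are too small. Among features that rose in mRNA, the median log2 fold change was 1.39 in mRNA and 0.47 in footprints. Among those that fell, it was -1.07 in mRNA and -0.94 in footprints. Both sets were picked by their mRNA change, which by itself makes the mRNA medians larger in size. The sign of the footprint change was that of the mRNA change in 73.8% of the features that rose and 86.2% of those that fell. The share over all 12694 features was not computed. For features with an average of at least 100 counts in both assays the Pearson correlation was 0.208.

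**Figure D3:**
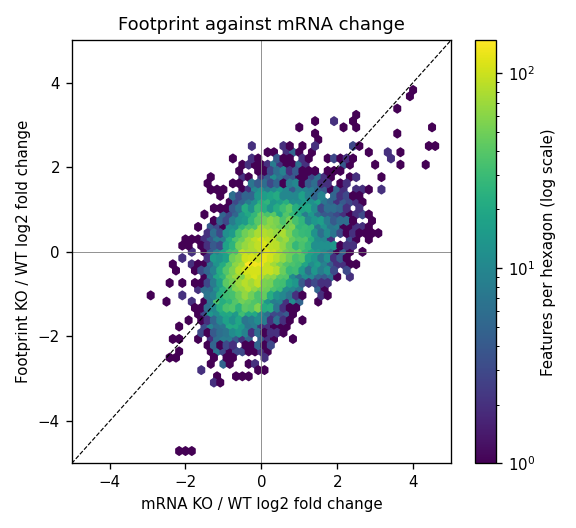
Footprint against mRNA KO to WT log2 fold change for 12694 features, as a density of hexagons (color on a log scale), with the line of equal change dashed. The regression of footprint on mRNA change has a slope of 0.51, with a Pearson correlation of 0.468.

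Translation efficiency, the quantity the study asked about, did not pass the main test for any single feature. Of 16417 features tested, 0 were called by the edgeR interaction test (smallest adjusted p 0.0605), and 1901 had an unadjusted p under 0.05. DESeq2 called 49 and limma voom with sample weights called 1359, of which 449 rose and 910 fell. The voom weights of WT footprint libraries 1, 2 and 3 were 0.57, 3.26 and 0.18. The WT footprint side of the voom calls thus rested mostly on library 2. With each numbered sample as a block, a pairing that the labels do not state, edgeR called 288, of which 118 rose and 170 fell. Without replicate 3 of WT the edgeR test called 172, and without replicate 1 of KO 7. In simulation with 200 changed features this test recovered 6.58% of those changed 4-fold, so changes of that size were mostly missed there. Recovery also depends on how many features change, which is not known for these data. For the 4 named transcripts the interaction log2 fold changes were -1.98 (SE 0.71) for uc007hjt.2, -1.18 (SE 0.63) for uc008cro.4, -0.05 (SE 0.52) for uc007jpg.2 and 1.62 (SE 0.46) for uc008pjn.2, with edgeR adjusted p of 0.305, 0.476, 0.981 and 0.226.

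As a trend over features, the translation efficiency of short features was lower in KO and that of long ones higher. This is a trend of the ratio. Over all features, footprint changes themselves ran against length (Spearman correlation -0.149), and mRNA changes more so (-0.389). For features with an average of at least 100 counts in both assays these correlations were 0.0438 and -0.751. The trend thus does not say that footprints moved toward long features. The median interaction log2 fold change was -0.43 in the shortest quartile (16 to 329), -0.14 in the second, -0.03 in the third and 0.14 in the longest (864 to 33458). The Spearman correlation with listed length was 0.255, and it was -0.00979 without WT mRNA libraries 1 and 2 and 0.0886 without replicate 3 of WT. For features with an average of at least 100 counts in both assays it was 0.682. Over all 16417 features, the footprint to mRNA ratio itself declined with length in each numbered sample of both genotypes. The slope was -0.40, -0.63 and -0.68 log2 units per doubling of length in WT and -0.63, -0.36 and -0.35 in KO. The means, -0.57 ± 0.15 in WT and -0.45 ± 0.16 in KO (SD, n = 3), differed by less than the spread between samples (difference 0.12, exact permutation p = 0.2). With replicates left out this difference ran from 0.068 to 0.212. It was 0.407 for features with an average of at least 100 counts in both assays. Among these features the ratio did not decline in KO sample 2, with slopes of -0.27 for footprints and -0.38 for mRNA. In KO sample 3 the slopes were close, at -0.43 and -0.40. In the other samples the footprint slope lay further below the mRNA slope.

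The underlying slopes of each assay varied between libraries. The log2 CPM of mRNA, which was not divided by length, rose by 0.62, 0.58 and 0.27 per doubling of length in WT libraries 1, 2 and 3. In KO it rose by 0.24, 0.22 and 0.18. Longer transcripts can yield more reads per molecule, so these slopes do not say that long mRNAs were more abundant. For features with an average of at least 100 counts in both assays, the slopes were 0.26, 0.19 and -0.21 in WT and -0.29, -0.38 and -0.40 in KO. The WT mean of 0.49 ± 0.19 and the KO mean of 0.21 ± 0.03 (SD, n = 3) differed by -0.28, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Footprint slopes were 0.22, -0.05 and -0.41 in WT and -0.38, -0.15 and -0.18 in KO, and their means, -0.08 ± 0.32 and -0.23 ± 0.13 (SD, n = 3), did not differ beyond the spread between libraries (exact permutation p = 0.5).

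**Figure D4:**
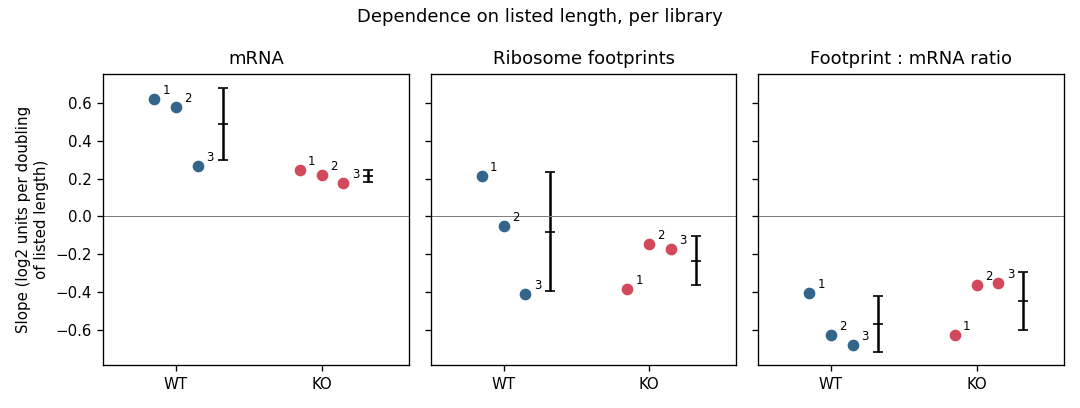
Slope of log2 CPM, or of the log2 footprint to mRNA ratio, on log2 listed length for each library or numbered sample (points, labelled by replicate number), with the group mean and SD (black, n = 3). WT mRNA libraries 1 and 2 (0.62 and 0.58) stand above WT library 3 (0.27) and the KO libraries (0.18 to 0.24).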

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

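Alternatives added after the data were seen were removing length trends, merging neighbours, leaving out the most abundant features and leaving out named libraries, and so were the length relations of mRNA and footprints alone; the others were planned. Where no cause is named, the cause was not tested. For mRNA (2145 calls), counts were 1281 with DESeq2, 1330 with neighbours merged (fewer features tested), 328 without WT mRNA libraries 1 and 2, and 652 to 4379 when replicates were left out; other alternatives stayed within 1.5 times, including 2205 with DESeq2 size factors and 2037 with length trends removed (1485 shared). For footprints (193 calls), counts were 1213 at an adjusted p under 0.10, 717 with DESeq2 (43.5% up, against 61.1%), 968 without the low-count filter, 82 with every transcript separate, 1583 with length trends removed (193 shared), 58 with neighbours merged, and 0 to 3057 when replicates were left out. For translation efficiency (0 calls), counts were 2 at an adjusted p under 0.10, 49 with DESeq2, 5 without the low-count filter, 1359 with voom sample weights, 34 with length trends removed, 2 with neighbours merged, 33 without WT footprint library 1, and 0 to 172 when replicates were left out.

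The labels do not say that numbers pair samples, and the data leave it open: deviations of same-numbered libraries correlated at 0.0341 to 0.523 between assays (3 of 6 over 0.1, 5 of 6 best with their own number, a hint from the data), -0.0127 to 0.0861 between WT and KO mRNA, and -0.357 to 0.111 between WT and KO footprints. With the replicate block, 2120 features were called in mRNA and 0 in footprints; in translation efficiency 288 with each numbered sample as a block (266 also called, in the same direction, by voom) and 0 with the number alone.

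With at least 100 counts on average (686 features), the correlation with length was -0.751 for mRNA, 0.0438 (reversed) for footprints and 0.682 for translation efficiency, and that of footprint with mRNA changes 0.208. Without WT mRNA libraries 1 and 2 it was -0.0941 for mRNA and -0.00979 (reversed) for translation efficiency. With replicates left out it was -0.327 to 0.0105 for footprints (reversed without WT replicate 1). Slope differences kept their sign in the alternatives run, but not their size. That of footprints (-0.153) ran from -0.0037 without WT replicate 1 to -0.318 without WT replicate 3. That of mRNA (-0.2755) ran from -0.210 without WT replicate 1 to -0.435 with at least 100 counts on average. That of the ratio (0.123) ran from 0.068 without WT replicate 3 to 0.407 with at least 100 counts on average. The named transcripts kept their mRNA calls in 15 of 15 alternatives; the footprint call held in 8 of 14 for uc007hjt.2, 7 for uc008cro.4 and 9 for uc007jpg.2, with folds of like size throughout (2.10 to 2.99, 1.76 to 2.39 and -2.75 to -2.07). Not run, because identifiers are not paired with genes: the gene-list tests, Caprin2, the crystallin share, mitochondrial scaling and the exclusion of crystallin, haemoglobin and muscle genes. In simulation with 200 changed features, the footprint test recovered 37.3% of 4-fold changes and the translation efficiency test 6.58%. These shares depend on depth, on spread and on how many features change.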

Other observations

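The tests of the length trend of WT mRNA libraries 1 and 2 and of genotype on the mRNA slopes, the splits for the length correlations of mRNA and footprints, and the descriptions of the most translated features, were chosen after the results were seen. The 10 features with the highest mean share of footprints held 16.0 ± 6.30% of footprint counts in WT and 15.1 ± 6.49% in KO (SD, n = 3, exact permutation p = 1). Their share of mRNA counts was 3.21 ± 1.82% in WT and 6.98 ± 0.966% in KO (SD, n = 3, exact permutation p = 0.1, the smallest possible; adjusted over 7 tests 0.35), with 5.94% to 7.85% in the KO libraries. WT mRNA libraries 1 and 2, which stand apart in length slope, held 2.06% and 2.27%, and WT library 3 held 5.31%, so the gap rests in part on those 2 libraries. Of the 10, 9 were short, with listed lengths from 164 to 206. Their mRNA log2 fold changes ran from 0.64 to 2.09, with 1 past the threshold (edgeR adjusted p from 0.0370 to 0.552). Their footprint log2 fold changes ran from -0.36 to 0.16, with adjusted p of at least 0.870. The interaction log2 fold changes, from -2.35 to -0.90, did not pass the test (adjusted p of at least 0.460). The remaining feature, of listed length 1444, had a mRNA log2 fold change of 0.84 (adjusted p = 0.325), a footprint log2 fold change of 1.84 (adjusted p = 0.241) and an interaction log2 fold change of 1.10 (adjusted p = 0.699). Several of these features probably share reads, so they do not count as 9 separate genes.

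Of the 460 features called in mRNA with each replicate left out, 414 were tested in footprints, and 348 of these (84.1%) had the same sign there. The share over all features was not computed.

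The first pattern is that mRNA changes ran against listed length. Sequencing depth as the cause is argued against, since thinning all mRNA libraries to 602243 counts kept 0.937 of the gap in slope between WT libraries 1 and 2 and the other 4. A length trend of WT libraries 1 and 2 alone and an effect of genotype cannot be told apart. The slope of WT library 3 lay 0.139 of their distance from the KO mean, but it is one of the slopes that showed the pattern and so does not test it, and 3 libraries a group cannot test genotype below an exact permutation p of 0.1. The trend does not account for all mRNA calls, since 2037 were made with it removed, 1485 of them shared.

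The second pattern is that WT footprint library 1 was close to the mRNA libraries, with a mean rank correlation of 0.618. Low depth is argued against, since the other footprint libraries, thinned to its total, stayed at least 0.0727 below it. mRNA fragments among the footprints may contribute: a mixture with 41% of the WT mRNA profile raised the held-out rank correlation by 0.081, from 0.699 to 0.780. That fit used WT footprint libraries 2 and 3 as the footprint profile. For each other library the profile was the remaining footprint libraries of both genotypes, without WT library 1. This gave 15% for WT library 2, where the held-out rank correlation rose from 0.7898 to 0.8515. It gave 0% for WT library 3 and 0%, 3% and 5% in KO. These shares rest on assumed profiles, which differ between the fits. No biological explanation was tested.

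The third pattern is that translation efficiency changes ran with listed length (Spearman correlation 0.255, and 0.682 with at least 100 counts on average). Footprint changes alone had correlations of -0.149 and 0.0438, and mRNA changes -0.389 and -0.751. The third pattern is therefore not separate from the first. mRNA fragments in WT footprint library 1 are argued against as the cause of the third pattern, since its correlation was 0.377 without that library. Without WT mRNA libraries 1 and 2 the correlation was -0.00979. Their slopes are the WT mRNA slopes farthest from KO, so leaving them out lowers the correlation whether a library trend or genotype is the cause. These causes cannot be told apart in this way, and WT was then represented in mRNA by library 3 alone. The correlation also fell to 0.0886 without both libraries of WT replicate 3. The mRNA changes then ran against length more strongly (-0.452, against -0.389), and so did the footprint changes (-0.327, against -0.149). The fall thus went with the footprint changes. It does not test whether the pattern rests on WT mRNA libraries 1 and 2. Of the 10 splits of the 6 numbered samples, 3 gave a correlation as large in size, the largest of the others being 0.442 in size, and 10 splits cannot give a share under 10%.

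Other splits of the samples were also run for the counts of calls. The real split of the mRNA libraries called 2145 features and the highest other split 0, so 1 of 10 splits gave as many. For footprints the real split called 193 and the highest other 0, again 1 of 10 splits. For translation efficiency all 10 splits called 0 with edgeR. The correlation of mRNA changes with length was -0.389 for the real split, and 4 of 10 splits, the real one included, gave one as large in size (largest of the others 0.493 in size). For footprints it was -0.149, and 8 of 10 splits gave one as large in size (largest of the others 0.560 in size). With 10 splits the share cannot fall under 10%.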
